A study of Homo sapiens with 22 samples.

How the data were processed

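RNA was sequenced from human blood monocytes of 11 volunteers, each cultured for 72 h at a normal and at a high sodium chloride level. There were 22 libraries, 11 per level, and each donor gave 1 library to each level. Sample labels give 140 mmol/L NaCl for normal salt and 190 mmol/L for high salt, while the series text gives 150 mM for the normal medium; the level is therefore called normal salt here. The labels place every library in batch 1.

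Per the series design text, polyadenylated RNA was made into paired-end Illumina libraries, reads were aligned to the human genome, QC3 was used for quality control and MultiRankSeq for expression analysis. TopHat2, DESeq2 and the GRCh38 build are named in the submitters' processing notes, without versions. The program that counted reads, the annotation release and whether counting used strand are not given in the sources used here. The deposited sheet named FPKM holds whole-number counts per Ensembl gene and not FPKM values: its column totals differ from 15465571 to 41893541, and DESeq2 fitted to it with donor and salt terms gave the deposited log2 fold changes to within 4e-09. A further deposited sheet gives the authors' log2 fold changes and adjusted p-values from a fit on protein-coding genes and from a fit on all features, per the file headers. Reads of near-identical paralogs or of processed pseudogenes, which ribosomal protein genes, FTL, FTH1, NCF1, the HLA genes and several histone genes have, can be split or lost in counting, and a gene and its antisense neighbour cannot be told apart without strand.

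The count columns were matched to samples by the library name in each label, and all 22 columns matched. Of 47756 features in the table, 71 on the Y chromosome or named XIST or TSIX were left out of every test. Symbols, coordinates and exons came from GENCODE release 44 on GRCh38, in which 1807 features had no entry; those kept the symbol of the deposited table. Genes with at least 1 CPM (counts relative to the library total, scaled by edgeR) in at least 11 libraries were tested, which left 13889 genes, 11984 of them protein-coding.

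The design written before the data were examined foresaw limma on FPKM values, and edgeR if the table turned out to hold counts. Counts were therefore scaled with TMM factors and tested with edgeR's quasi-likelihood F test (edgeR 4.0.16, limma 3.58.1, R 4.3.3), with donor as a block and salt level as the term of interest. Fold changes are log2, high minus normal salt, with standard errors (SE). Adjusted p-values are Benjamini-Hochberg over all genes tested with a threshold of 0.05. CPM values are means ± SD over 11 libraries. DESeq2 1.42.0 served as an alternative. The pairing comes from the donor numbers in the titles: deviations from the group means correlated between the libraries of each donor at 0.42 to 0.76 (median 0.56, 11 pairs), against a median of -0.07 between different donors. No pair of libraries of a group differed by as little as sampling noise (smallest chi-square per degree of freedom 42.8 over 110 pairs).

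A collection of 38 gene lists was fixed before the data were examined. Lists with at least 3 tested members were compared with the other genes by limma's camera on log2 CPM (prior count 2, preset inter-gene correlation 0.01), with Benjamini-Hochberg adjustment over lists. Camera with an estimated correlation and limma's fry were run beside it. Fry asks whether a list's own genes move on balance in 1 direction and does not compare the list with other genes. Genes named by size are the 10 highest and the 10 lowest log2 fold changes among genes past the threshold that changed in the same direction in at least 10 of 11 donors and had a mean CPM (in place of FPKM) of at least 5 in at least one level. Genes with no symbol, Y-linked genes, XIST, TSIX, HLA and KIR genes, immunoglobulin and T cell receptor segments, pseudogenes and genes that the deposited table does not class as protein-coding were left out of that choice. Each list is represented by up to 4 called members with the largest absolute change, or by its 2 highest-expressed members where none was called. A set of 19 genes of interest in salt and monocyte biology is given whatever it showed. Library measures were compared between levels by exact two-sided sign-flip tests over donors, adjusted over 7 measures.

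The test was tried on simulated counts for 13889 genes of the high against normal salt comparison. It recovered 42% of 50 genes given a log2 change of 0.5, 86% of those given 1, 100% of those given 2 and 98% of those given 3, with 12 false calls among 175. A simulated list of 25 shifted genes gave a camera p of 1.9e-84, and 2 of 100 random lists fell below 0.05. The simulated genes were drawn independently, so this does not show how camera behaves for lists whose genes move together. The totals make counting error small against the spread between donors for genes above the filter, and intervals on shares of counts cover counting error only. Alternatives planned ahead covered the donor block, low-count filters, scaling, the test, library quality weights and the omission of each donor in turn. Those added after the data were seen were DESeq2, limma trend, library totals without TMM factors, mitochondrial genes left out, the omission of donors 5 and 9 together, protein-coding genes alone and thinning to the smallest library.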

Results

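Monocytes, the circulating white blood cells that can become macrophages, were isolated from the blood of 11 volunteers by negative selection and cultured for 72 h in medium with a normal or a raised sodium chloride level. Polyadenylated RNA was sequenced from each culture, so that every donor contributed 1 normal salt and 1 high salt library. Total counts ran from 15465571 to 36882405 in the 11 normal salt libraries and from 30155606 to 41893541 in the 11 high salt libraries. High salt libraries were the larger in 9 of 11 donors (mean log2 ratio 0.33, exact sign-flip p = 0.0107, adjusted p = 0.0251 over 7 library measures). Mitochondrial transcripts took 24.8% of counts in the normal salt library of donor 5 (95% Wilson interval 24.82 to 24.87), and 12.5% (12.51 to 12.54) and 33.0% (32.96 to 32.99) in the normal and high salt libraries of donor 9. They took less than 10% in the other 19 libraries. This share was higher with high salt in 7 of 11 donors (exact sign-flip p = 0.734), and without donors 5 and 9, left out after their values were seen, in 6 of 9 (unadjusted p = 0.0469). Gene-wise responses to salt correlated between donors at 0.26 to 0.75 (median 0.54, 55 pairs).

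The comparison of salt levels asks which transcripts of monocytes differ after culture in a medium with more salt. High salt raised transcripts of SLC5A3, the sodium-coupled myo-inositol transporter that cells use to take up an osmolyte, by 4.62 ± 0.26 on the log2 scale (SE, n = 11), from 88.0 ± 65.8 to 2003 ± 1575 CPM (SD). The chemokine receptor CCR2 rose by 4.93 ± 0.48 and fibronectin (FN1) by 4.20 ± 0.72. All 27 tested interferon-stimulated genes rose, and so did the chemokine genes CXCL5 and CCL20. Among the genes that fell were 13 of 19 of costimulation and class II presentation, 15 of 19 antioxidant, 20 of 29 macrophage and lysosome, 49 of 61 ribosomal protein, 8 of 15 iron handling and 34 of 48 oxidative phosphorylation genes. As sets, none of the lists passed camera with an estimated correlation (smallest adjusted p = 0.177). In all, 5602 of 13889 tested genes (40.3%) passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 2714 higher and 2888 lower in high salt. Of those, 1130 rose and 1115 fell at least 1.5-fold, 467 rose and 335 fell at least 2-fold, and 41 rose and 3 fell at least 8-fold. The direction was the same in 11 of 11 donors for 1016 of the genes higher and 1233 of the genes lower. Without the donor block the test called 1185 genes higher and 1064 lower. Library totals in place of TMM scaling moved all genes by a median of 0.10 and gave 3874 higher and 1917 lower (66.9% against 48.4% of calls higher).

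**Figure D1:**
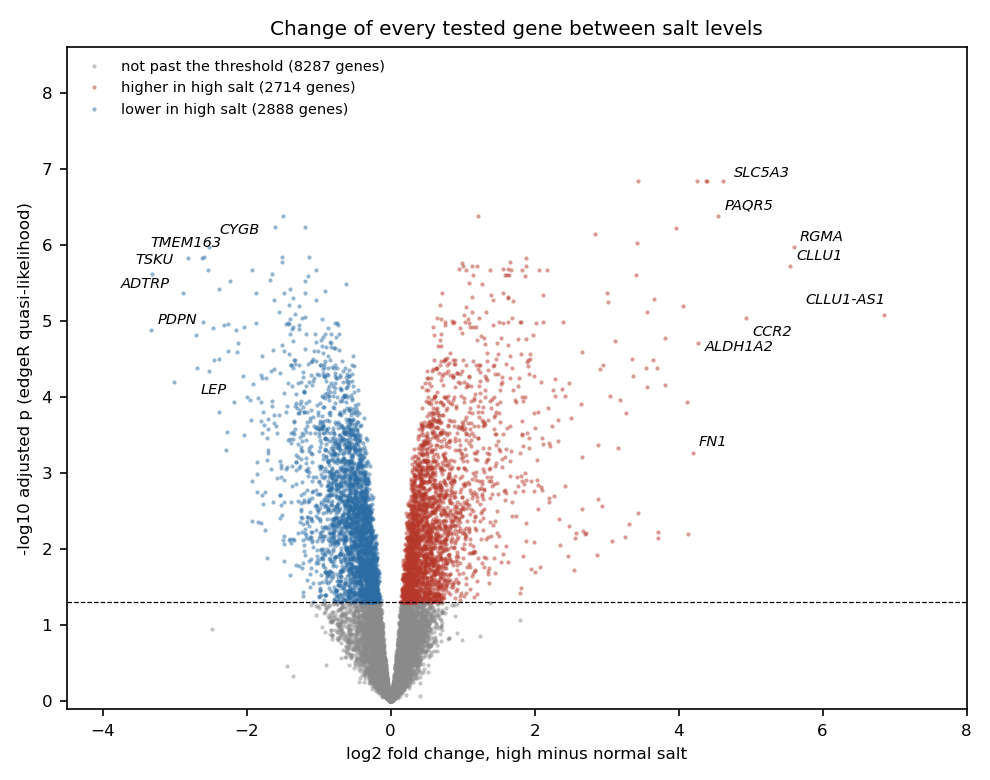
Change of every tested gene, with the log2 fold change (high minus normal salt) on the x axis and -log10 of the adjusted p from edgeR's quasi-likelihood test on the y axis. Points are genes, red for the 2714 higher, blue for the 2888 lower and grey for the others, and the dashed line marks an adjusted p of 0.05; the change is 6.85 for CLLU1-AS1 and -3.32 for PDPN and TSKU.

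The 10 largest rises that met the naming rule were those of SLC5A3, CCR2, FN1, CLLU1-AS1 (6.85 ± 0.66), CLLU1 (5.54 ± 0.44) and 5 others. These were the axon guidance molecule RGMA (5.60 ± 0.40), the membrane progestin receptor PAQR5 (4.55 ± 0.29), the protocadherin PCDHGC3 (4.40 ± 0.25), the mitochondrial arginase ARG2 (4.38 ± 0.25) and the retinoic acid-producing enzyme ALDH1A2 (4.27 ± 0.47). Each was higher in 11 of 11 donors, except FN1 in 10, with adjusted p from 1.47e-07 for SLC5A3, PCDHGC3 and ARG2 to 5.39e-04 for FN1. At low normal salt levels, RGMA went from 0.629 ± 0.551 to 56.4 ± 102 CPM and ARG2 from 0.699 ± 0.238 to 18.4 ± 18.2. ALDH1A2 went from 3.35 ± 2.24 to 88.6 ± 105 and FN1 from 151 ± 172 to 1627 ± 1625. The 10 largest falls were those of podoplanin (PDPN, -3.32 ± 0.35, from 73.9 ± 41.6 to 12.2 ± 17.0 CPM), TSKU (-3.32 ± 0.28), ADTRP (-2.88 ± 0.26), the zinc transporter TMEM163 (-2.82 ± 0.21) and 6 others. These were the gap junction protein GJB2 (-2.62 ± 0.20), APBA1 (-2.60 ± 0.26), RARRES1 (-2.59 ± 0.19), the matrix protein SPARC (-2.54 ± 0.21), cytoglobin (CYGB, -2.53 ± 0.18) and leptin (LEP, -2.52 ± 0.31). LEP was lower in 10 donors and the other 9 in 11 of 11, with adjusted p from 1.06e-06 for CYGB to 4.50e-05 for LEP.

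On GRCh38, SLC5A3 (ENSG00000198743) lies on chromosome 21 from 34073578 to 34106260, RGMA on chromosome 15 from 93035271 to 93089211 and CCR2 on chromosome 3 from 46353864 to 46360940. PAQR5 lies on chromosome 15 from 69298912 to 69407780 and ARG2 on chromosome 14 from 67619920 to 67651708. FN1 lies on chromosome 2 from 215360440 to 215436073, PDPN on chromosome 1 from 13583465 to 13617957 and TSKU on chromosome 11 from 76782251 to 76798153. CCR2, FN1, PDPN, TSKU, TMEM163, GJB2 and LEP share no exon sequence with another annotated gene. Several other values are uncertain because exons overlap and the strand of counting is unknown. Exons of SLC5A3 overlap those of MRPS6 on the same strand between 34073578 and 34103519. CLLU1 and CLLU1-AS1 lie on opposite strands of chromosome 12 and overlap from 92422547 to 92422636. The deposited table classes both as protein-coding and GENCODE as long non-coding RNAs. ALDH1A2 exons overlap AQP9 on the opposite strand of chromosome 15 between 58138447 and 58166796. ARG2 overlaps VTI1B, CYGB overlaps PRCD and RARRES1 overlaps MFSD1. PCDHGC3 shares its last exons with the other gamma protocadherins.

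**Figure D2:**
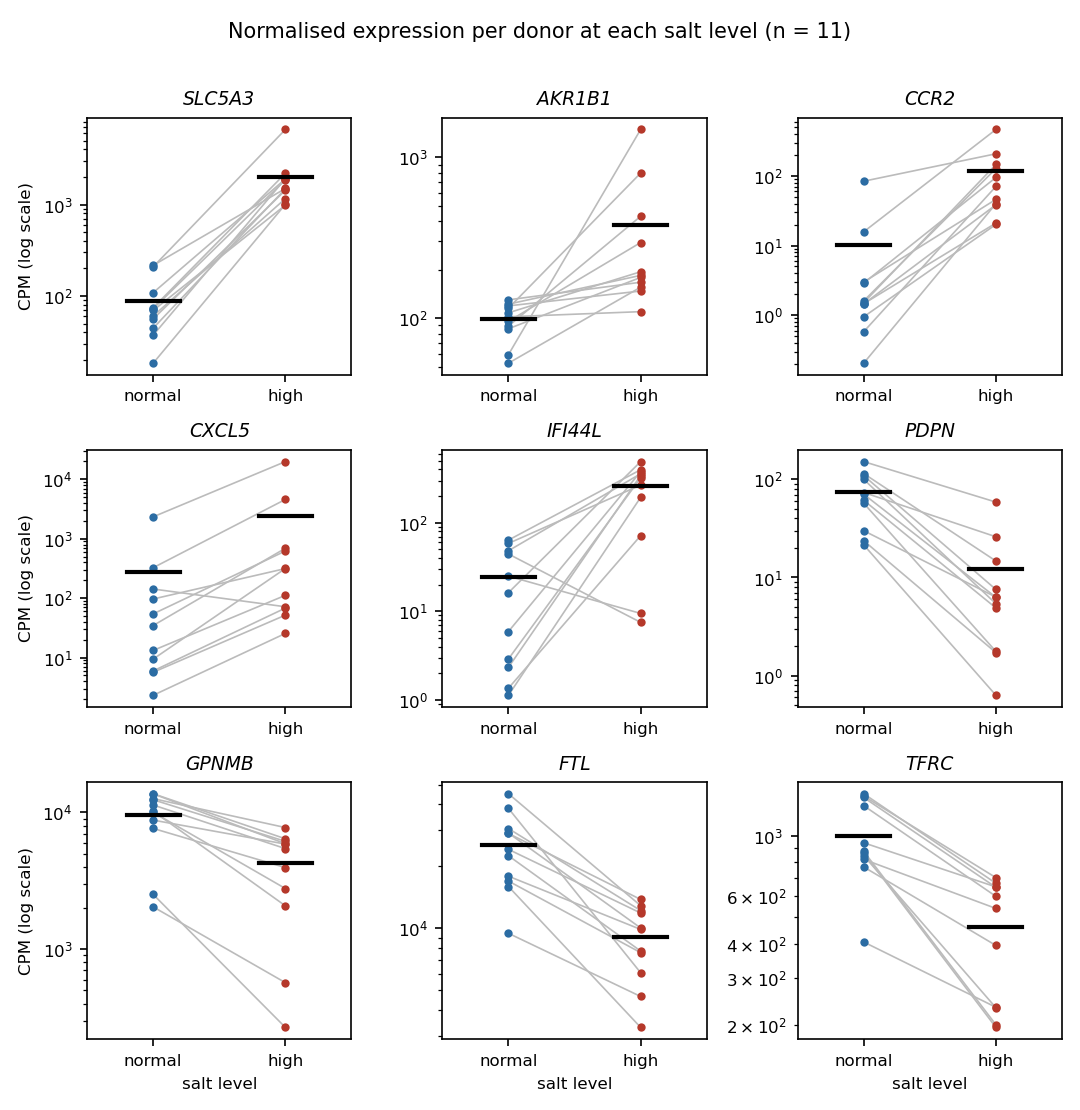
Expression of 9 genes at each salt level, in CPM on a log axis; each point is 1 library, grey lines join the libraries of a donor and black bars are means over 11 libraries. SLC5A3, AKR1B1 and CCR2 were higher in high salt in 11 of 11 donors, CXCL5 in 10 and IFI44L in 9, while PDPN, GPNMB, FTL and TFRC were lower in 11 of 11.

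Of 9 tested osmoprotection genes, targets of the tonicity-responsive factor NFAT5 and aquaporins, 6 rose and 2 fell (6 and 2 adjusted over the list alone), with a median log2 change of 1.08. After SLC5A3, the largest rises were those of the water and glycerol channel AQP9 (1.45 ± 0.18), whose exons overlap ALDH1A2, of AKR1B1, the aldose reductase that makes sorbitol (1.39 ± 0.35, from a mean of 98.1 to one of 377 CPM, adjusted p = 0.00675), and of the betaine transporter SLC6A12 (1.33 ± 0.38). NFAT5 itself rose by 0.52 ± 0.08 in 11 of 11 donors (adjusted p = 2.21e-04), and the salt-responsive kinase SGK1 fell, by -0.58 ± 0.14 in 10 donors (adjusted p = 0.00470). The list passed camera (adjusted p = 0.00822) but not camera with an estimated correlation (adjusted p = 0.239), and it passed fry (adjusted p = 3.54e-06). Among 15 tested sodium transport genes, 4 rose and 1 fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.219, fry adjusted p = 9.32e-04). The sodium pump subunit ATP1B3 (1.02 ± 0.10) and the kinase OXSR1 (0.38 ± 0.07) were among the risers, and STK39 fell (-0.50 ± 0.18, adjusted p = 0.0362, lost in 10 alternative settings). The epithelial sodium channel was near the detection limit: SCNN1D gave 1.93 ± 1.07 CPM in normal and 2.87 ± 2.64 in high salt (0.44 ± 0.17, adjusted p = 0.0532), a value that passed the threshold in 8 alternative settings and in the authors' deposited protein-coding fit (adjusted p = 0.0271), though not in their fit on all features (adjusted p = 0.0594). Summed over 11 libraries, SCNN1A, SCNN1B and SCNN1G gave 272, 149 and 168 counts in normal and 400, 213 and 165 in high salt, under the expression filter. These sums are not scaled for library size. In the edgeR fit without that filter their log2 changes were 0.08, -0.42 and -0.98 (adjusted p = 0.928, 0.633 and 0.0630).

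The interferon response list, antiviral genes induced by interferons, had the highest median of the 35 lists tested, 2.48: 27 of 27 tested members rose (27 adjusted over the list alone). The largest rises were those of IFI44L (4.13 ± 1.04, from 24.5 ± 24.7 to 258 ± 165 CPM), RSAD2 (3.71 ± 0.95), IFIT1 (3.71 ± 0.92) and IFIT3 (3.31 ± 0.79), each with an adjusted p of 0.0047 to 0.0071 and higher in 9 of 11 donors. The median over the list was above 0 in 9 donors, between -1.50 and 4.23 over all 11. Camera gave an adjusted p of 2.38e-09, camera with an estimated correlation an adjusted p = 0.448, and fry an adjusted p of 0.00615. The list member CXCL10, named after its values were seen and under the expression filter, had 98 counts in all in normal and 1411 in high salt. These sums are not scaled for library size. Beside it, the T cell marker IL7R (-1.28 ± 0.23) and the NK cell marker NKG7 (-0.79 ± 0.20) fell, while 17 of the 25 listed T and NK cell markers were under the filter.

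Of 25 tested NF-kB cytokines and targets, 16 rose and 2 fell (16 and 2 adjusted over the list alone), with a median of 0.94. The chemokines CCL20 (3.64 ± 0.42, from 7.46 ± 20.7 to 72.2 ± 139 CPM), CXCL5 (3.19 ± 0.44) and CCL7 (2.57 ± 0.64) rose most, followed by IL1B (2.20 ± 0.47, from 139 ± 320 to 1030 ± 2100 CPM, adjusted p = 0.00242, higher in 10 of 11 donors). TNF rose by 1.23 ± 0.15 at a low level, from 4.30 ± 2.85 to 9.76 ± 5.78 CPM (adjusted p = 3.82e-05). IL6 did not reach the expression filter and gave 917 counts in all in normal and 6760 in high salt, not scaled for library size. Fewer than 11 of the 22 libraries reached 1 CPM, so these sums do not describe a typical donor. In the edgeR fit without the filter its log2 change was 2.39 (adjusted p = 7.38e-40). There IL1B had an adjusted p of 1.08e-42, so p-values of that fit cannot be set beside those of the filtered fit. The list passed camera (adjusted p = 7.65e-05), not camera with an estimated correlation (adjusted p = 0.360), and passed fry (adjusted p = 5.62e-04). Of 12 tested inflammasome genes, 4 rose and 2 fell (6 and 3 adjusted over the list alone; camera adjusted p = 0.383, fry adjusted p = 0.0108). They were led by IL1B, the ATP receptor P2RX7 (1.03 ± 0.10) and NLRP1 (0.75 ± 0.22), with IL18 lower (-0.75 ± 0.18). NLRP3 stood at 62.8 ± 22.2 and 82.1 ± 46.6 CPM (0.27 ± 0.15, adjusted p = 0.167). Of 20 immediate early genes 7 rose and 1 fell (7 and 1 adjusted over the list alone), with EGR2 (1.69 ± 0.17), DUSP2 (1.52 ± 0.21), FOS (1.07 ± 0.14) and FOSL1 (0.96 ± 0.35, lost in 10 alternative settings) ahead. That list passed camera at an adjusted p of 0.0167, against an adjusted p = 0.426 with an estimated correlation, 0.0517 without the donor block and 0.0548 with the stricter filter. Fry gave an adjusted p of 0.00107.

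Of 7 NADPH oxidase genes, which encode the oxidant-producing complex of phagocytes, RAC2 (0.66 ± 0.14) and the catalytic subunit CYBB (0.36 ± 0.11, from 1099 ± 369 to 1444 ± 591 CPM, adjusted p = 0.0209) rose and none fell (2 and 0 adjusted over the list alone; camera adjusted p = 0.561, fry adjusted p = 0.195). JAK-STAT and SMAD3 genes moved both ways, 5 of 22 up and 5 down (5 and 5 adjusted over the list alone; camera adjusted p = 0.955, fry adjusted p = 0.562), with a median of -0.00 and a mean of 0.02. SMAD3, a mediator of TGF-beta signals, rose by 1.63 ± 0.15, from 20.4 ± 12.7 to 64.5 ± 47.0 CPM in 11 of 11 donors (adjusted p = 4.96e-06). TYK2 (0.67 ± 0.10), STAT2 (0.64 ± 0.11) and, just past the threshold, JAK2 (0.30 ± 0.11, adjusted p = 0.0452, lost in 11 alternative settings) rose too, whereas the suppressor SOCS2 fell (-1.78 ± 0.37). STAT3 differed by 0.05 ± 0.07 (adjusted p = 0.582).

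In the list of costimulation and class II presentation, 13 of 19 members fell and none rose (13 and 0 adjusted over the list alone; median -1.03). HLA-DQA1 (-1.70 ± 0.26), HLA-DPB1 (-1.48 ± 0.29) and HLA-DPA1 (-1.31 ± 0.26), chains of the molecules that present antigen to helper T cells, fell in 11 of 11 donors, as did the inhibitory ligand PDCD1LG2 (-1.54 ± 0.19). CD86 (-0.17 ± 0.10, adjusted p = 0.170) and CD83 (0.05 ± 0.22, adjusted p = 0.873), which mark antigen-presenting cell activation, did not pass the test. The list gave a camera adjusted p of 5.45e-05, with an estimated correlation an adjusted p = 0.444, and a fry adjusted p of 0.00108. Of 9 dendritic cell markers 5 fell and 1 rose (6 and 1 adjusted over the list alone; median -0.72). LAMP3 (-1.76 ± 0.27), IRF4 (-1.25 ± 0.21) and FLT3 (-1.10 ± 0.26) went down and the chemokine receptor XCR1 went up (1.80 ± 0.64, adjusted p = 0.0371, lost in 9 alternative settings). This list had a camera adjusted p of 0.0169, an adjusted p = 0.275 with an estimated correlation and a fry adjusted p of 2.06e-04.

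Macrophage differentiation and lysosome genes fell in 20 of 29 cases and rose in 3 (20 and 3 adjusted over the list alone; median -0.56). The proton pump subunit ATP6V0D2 (-2.31 ± 0.24), the glycoprotein GPNMB (-1.42 ± 0.23, from 9537 ± 4070 to 4288 ± 2524 CPM) and the protease LGMN (-1.23 ± 0.24) fell in 11 of 11 donors, and osteopontin (SPP1) rose (1.45 ± 0.34). Camera gave an adjusted p of 5.45e-05, an estimated correlation an adjusted p = 0.444, and fry an adjusted p of 0.00145. Classical monocyte markers rose in 5 of 14 cases and fell in none (5 and 0 adjusted over the list alone; camera adjusted p = 0.0633, fry adjusted p = 5.89e-04). The camera value was 0.0491 without donor 3, 0.0457 without donor 5 and 0.0481 without donor 7. Among them were CCR2, VCAN (0.84 ± 0.29, lost in 8 alternative settings), the lipopolysaccharide co-receptor CD14 (0.75 ± 0.18, from 730 ± 393 to 1356 ± 959 CPM) and S100A12 (0.57 ± 0.14). Of 9 non-classical monocyte markers 2 rose, TCF7L2 (1.82 ± 0.15) and VMO1 (1.49 ± 0.31), and 2 fell, CDKN1C (-0.68 ± 0.13) and SIGLEC10 (-0.54 ± 0.17) (2 and 2 adjusted over the list alone; camera adjusted p = 0.797, fry adjusted p = 0.243; median -0.04, mean 0.22). Alternative activation genes divided into 7 higher and 7 lower of 18 (7 and 8 adjusted over the list alone; camera adjusted p = 0.981, fry adjusted p = 0.936). The scavenger receptors MARCO (2.25 ± 0.30) and MSR1 (1.80 ± 0.31) and the transglutaminase TGM2 (1.48 ± 0.29) rose, and the selenium carrier SELENOP fell (-1.75 ± 0.36). Among 9 efferocytosis receptors and ligands, which serve the uptake of dead cells, AXL rose (1.11 ± 0.29, from 18.4 ± 19.2 to 37.8 ± 27.6 CPM, adjusted p = 0.00736), and STAB1 (-1.27 ± 0.15), GAS6 (-1.04 ± 0.26) and CD300LF (-0.51 ± 0.11) fell (1 and 3 adjusted over the list alone; camera adjusted p = 0.396, fry adjusted p = 0.180).

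Iron handling genes fell in 8 of 15 cases and rose in none (9 and 0 adjusted over the list alone; median -0.49). Ferritin light chain FTL, the most abundant of them, went from 25341 ± 10431 to 9079 ± 3486 CPM (-1.47 ± 0.20), and the hormone hepcidin (HAMP, -1.74 ± 0.22), the transferrin receptor TFRC (-1.21 ± 0.16) and the reductase STEAP3 (from 37.8 ± 23.8 to 19.8 ± 15.5 CPM) fell as well. The list had a camera adjusted p of 0.00317, an adjusted p = 0.177 with an estimated correlation and a fry adjusted p of 3.54e-06. Of 19 NRF2 and antioxidant genes 15 fell and none rose (16 and 0 adjusted over the list alone; median -0.58). NQO1 (-1.45 ± 0.21), thioredoxin (TXN, -1.09 ± 0.21), heme oxygenase HMOX1 (-1.05 ± 0.17) and catalase (CAT, -0.97 ± 0.18) fell in 11 of 11 donors. Camera gave an adjusted p of 1.52e-05, an estimated correlation an adjusted p = 0.360, and fry an adjusted p of 5.62e-04.

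Ribosomal protein genes fell in 49 of 61 cases and rose in none (55 and 0 adjusted over the list alone), with a median of -0.54 that was -0.34 without donors 5 and 9. RPL5 (-0.91 ± 0.15), RPL10 (-0.91 ± 0.15), RPSA (-0.87 ± 0.17) and RPLP0 (-0.87 ± 0.15) fell in 11 of 11 donors. The share of counts from these genes went from 2.12% ± 0.53 to 1.55% ± 0.49 (SD, n = 11), lower in 10 of 11 donors (exact sign-flip p = 0.00195, adjusted p = 0.0137). Camera gave an adjusted p of 5.28e-13, an estimated correlation an adjusted p = 0.561, and fry an adjusted p of 0.0108. Nuclear-encoded oxidative phosphorylation genes fell in 34 of 48 cases and rose in 1 (36 and 1 adjusted over the list alone; median -0.34). ATP5MC1 (-0.67 ± 0.12), NDUFB5 (-0.66 ± 0.12), UQCRB (-0.58 ± 0.09) and UQCRC2 (-0.56 ± 0.11) fell most (camera adjusted p = 2.21e-08, fry adjusted p = 0.00192, but adjusted p = 0.448 with an estimated correlation). Of 13 mitochondrially encoded transcripts 6 fell and none rose (6 and 0 adjusted over the list alone), MT-ND6 (-0.95 ± 0.28), MT-CO3 (-0.80 ± 0.25), MT-ND5 (-0.71 ± 0.24, lost in 7 alternative settings) and MT-CO1 (-0.68 ± 0.21) ahead. That list had a camera adjusted p of 0.0339, an adjusted p = 0.770 with an estimated correlation and a fry adjusted p of 0.195, and its camera adjusted p was 0.135 without donor 5, 0.0552 without donor 6 and 0.0577 without donor 7. It was 0.243 with quantile normalization and 0.0536 with the stricter filter. The list median was above 0 in 3 of 11 donors. By contrast, the share of counts from all mitochondrial transcripts, taken without TMM factors, was higher with high salt in 7 of 11. That share counts every gene of the mitochondrial chromosome and not only the 13 of the list. The measures thus differ in genes as well as in scaling. In the normal salt library of donor 5 the share was 24.8%, where all protein-coding genes together took 74.4% of counts. Which of these differences matters was not tested.

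Glycolysis and hypoxia genes rose in 12 of 28 cases and fell in 2 (12 and 2 adjusted over the list alone; median 0.25). The oxygen sensor EGLN3 (1.97 ± 0.21), VEGFA (1.01 ± 0.18), hexokinase HK1 (0.89 ± 0.12) and the hypoxia factor HIF1A (0.89 ± 0.19) rose most (camera adjusted p = 0.00365, fry adjusted p = 0.0327, but adjusted p = 0.617 with an estimated correlation). ER chaperone and unfolded protein response genes fell in 9 of 18 cases and rose in none (9 and 0 adjusted over the list alone), among them HYOU1 (-0.81 ± 0.15), HSP90B1 (-0.71 ± 0.14), HERPUD1 (-0.65 ± 0.10) and CANX (-0.63 ± 0.14). By camera the adjusted p was 5.63e-04, with an estimated correlation the adjusted p = 0.583, and by fry the adjusted p was 0.0220. Heat shock genes went both ways, 3 of 14 up and 4 down (4 and 4 adjusted over the list alone; camera adjusted p = 0.966, fry adjusted p = 0.846): the mitochondrial chaperonins HSPD1 (-0.59 ± 0.10) and HSPE1 (-0.56 ± 0.11) fell while HSPH1 (0.54 ± 0.10) and HSPA6 (0.51 ± 0.08) rose. ATF4 and amino acid response genes fell in 6 of 22 cases and rose in 1 (5 and 0 adjusted over the list alone; camera adjusted p = 0.315, fry adjusted p = 0.219), with NUPR1 (-0.91 ± 0.28), SLC7A11 (-0.61 ± 0.17), SHMT2 (-0.57 ± 0.12) and MTHFD2 (-0.55 ± 0.17) lowest.

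Cholesterol synthesis genes rose in 5 of 24 cases and fell in 4 (5 and 4 adjusted over the list alone; camera adjusted p = 0.667, fry adjusted p = 0.501), with STARD4 (1.20 ± 0.10) and SQLE (0.91 ± 0.26) higher and LSS (-0.94 ± 0.11) lower. Of 18 LXR and PPARG lipid handling genes 6 fell and 2 rose (6 and 2 adjusted over the list alone; camera adjusted p = 0.170, fry adjusted p = 0.00745). PLTP (-1.25 ± 0.16) and the receptor NR1H3 (-1.24 ± 0.21) fell, and PPARG (1.05 ± 0.10) and ANGPTL4 (1.05 ± 0.37, lost in 10 alternative settings) rose. Complement and coagulation genes fell in 9 of 20 cases and rose in 6 (10 and 6 adjusted over the list alone; camera adjusted p = 0.195, fry adjusted p = 0.00615). Tissue factor (F3, 3.16 ± 0.53) and the C1 inhibitor SERPING1 (1.61 ± 0.43) rose, and the plasminogen activator PLAU (-2.04 ± 0.21) and C1QC (-1.54 ± 0.27) fell. Eicosanoid genes rose in 5 of 15 cases and fell in 6 (5 and 6 adjusted over the list alone; camera adjusted p = 0.635, fry adjusted p = 0.0623). The prostaglandin E synthesis genes PTGES (1.81 ± 0.62, lost in 7 alternative settings) and PTGS2 (1.10 ± 0.25) were up, and the lipoxygenase ALOX15B (-1.93 ± 0.16) and the phospholipase PLA2G7 (-1.66 ± 0.20) were down. Of 27 integrin, matrix and protease genes 8 rose and 8 fell (8 and 10 adjusted over the list alone; camera adjusted p = 0.909, fry adjusted p = 0.790; median -0.08, mean 0.23), with FN1, MMP1 (4.11 ± 0.57) and MMP8 (2.00 ± 0.29) higher and ITGB5 (-2.26 ± 0.23) lower.

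Genes of p53 and growth arrest rose in 8 of 19 cases and fell in 4 (9 and 4 adjusted over the list alone; camera adjusted p = 0.349, fry adjusted p = 0.251). PHLDA3 rose (0.89 ± 0.33, adjusted p = 0.0434, lost in 8 alternative settings) and GADD45B (-1.40 ± 0.14), GADD45G (-0.87 ± 0.27) and GADD45A (-0.71 ± 0.20) fell. Of 18 proliferation genes 5 rose and none fell (5 and 0 adjusted over the list alone; camera adjusted p = 0.361, fry adjusted p = 0.370). TYMS (0.90 ± 0.20), MCM7 (0.80 ± 0.11), CCNB2 (0.76 ± 0.26, lost in 6 alternative settings) and MCM5 (0.51 ± 0.08) led them, at levels of 1.15 to 65.2 CPM. Of the metallothionein list only SLC30A1 (-0.14 ± 0.11, adjusted p = 0.338) and MT2A (0.41 ± 0.54, adjusted p = 0.570) reached the filter, and neither passed the test.

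Of 5 T cell markers tested 1 fell, IL7R, which monocytes can also express (1 adjusted over the list alone; camera adjusted p = 0.122, fry adjusted p = 0.0312), and of 3 NK cell markers 1 fell, NKG7 (1 adjusted over the list alone; camera adjusted p = 0.744). Of 2 testable B cell markers 1 rose and 1, CD22, fell (-1.51 ± 0.11) (1 and 1 adjusted over the list alone). Of 8 platelet markers TUBB1 rose (0.53 ± 0.14) and TREML1 fell, from 2.20 ± 0.770 to 1.15 ± 0.587 CPM (1 each adjusted over the list alone; camera adjusted p = 0.635, fry adjusted p = 0.378). Of 13 granulocyte markers CLC fell (-1.72 ± 0.49) at 3.27 ± 3.56 to 1.09 ± 1.59 CPM and none rose (1 and 0 adjusted over the list alone; camera adjusted p = 0.796, fry adjusted p = 0.719). Of 8 red cell markers 0 reached the filter. The most counted, named after their values were seen, were HBD, with 304 counts over the normal and 266 over the high salt libraries, and SLC4A1, with 227 and 279.

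**Figure D3:**
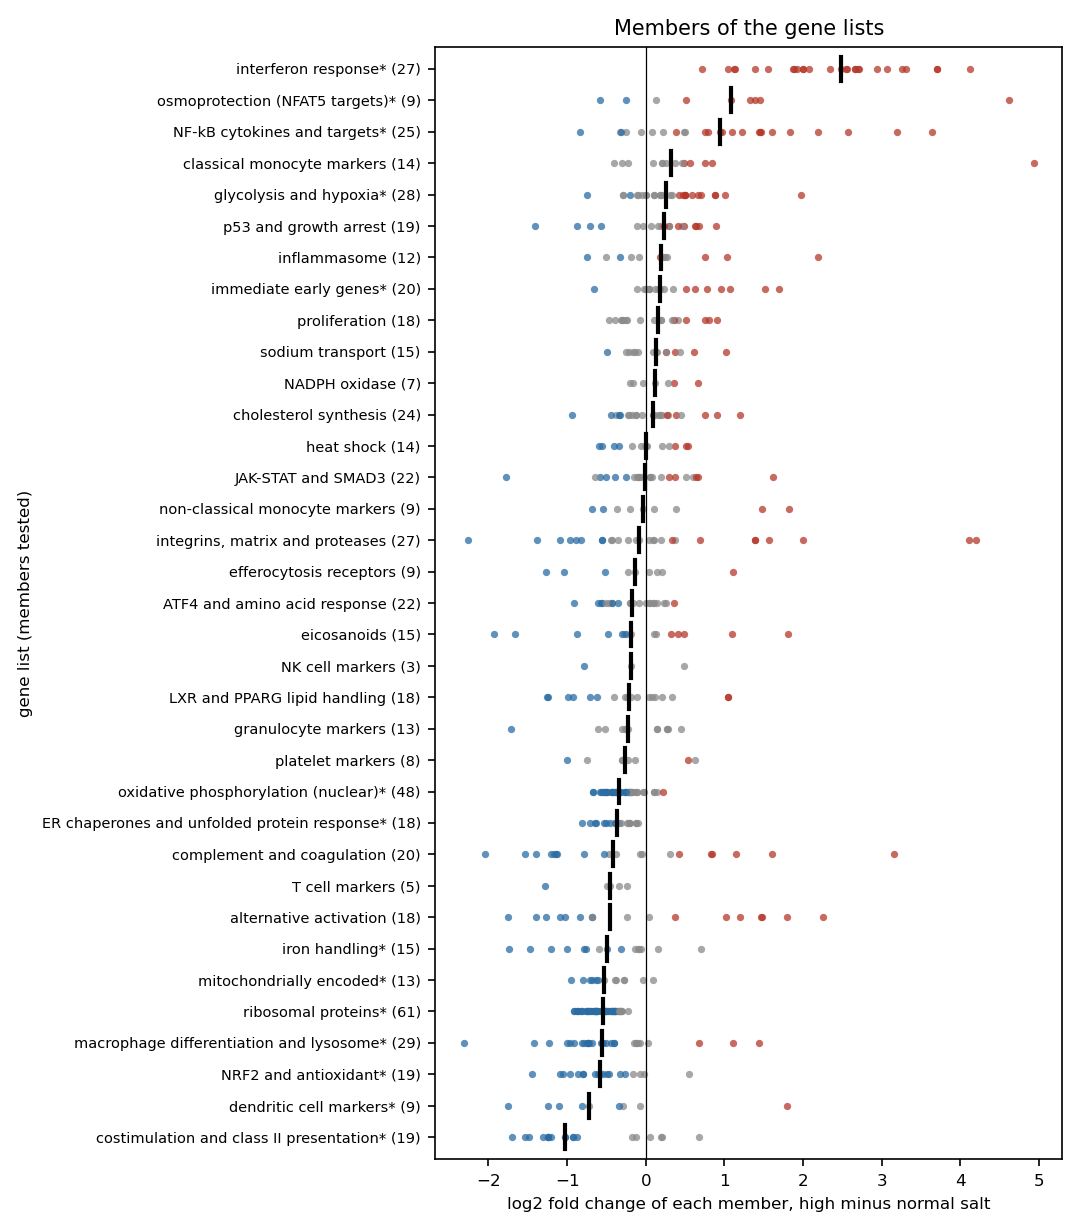
Log2 fold changes (x axis, high minus normal salt) of the tested members of 35 gene lists (y axis, with the number tested); each point is 1 gene, red if higher, blue if lower and grey if not past an adjusted p of 0.05 in edgeR's quasi-likelihood test, black bars are list medians, and an asterisk marks the 14 lists past camera with the preset correlation. Medians run from 2.48 for the interferon response to -1.03 for costimulation and class II presentation.

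Camera with the preset correlation placed 14 of 35 lists past the threshold, 5 higher and 9 lower. It placed at least as many past it in 6 of 100 swaps of the salt labels within donors, the real labels included. The median over the 99 other swaps was 8 lists. None of the 14 passed with an estimated correlation (smallest adjusted p = 0.177, for iron handling). Fry called 19 lists, including 13 of the 14 and not the mitochondrially encoded list.

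**Figure D4:**
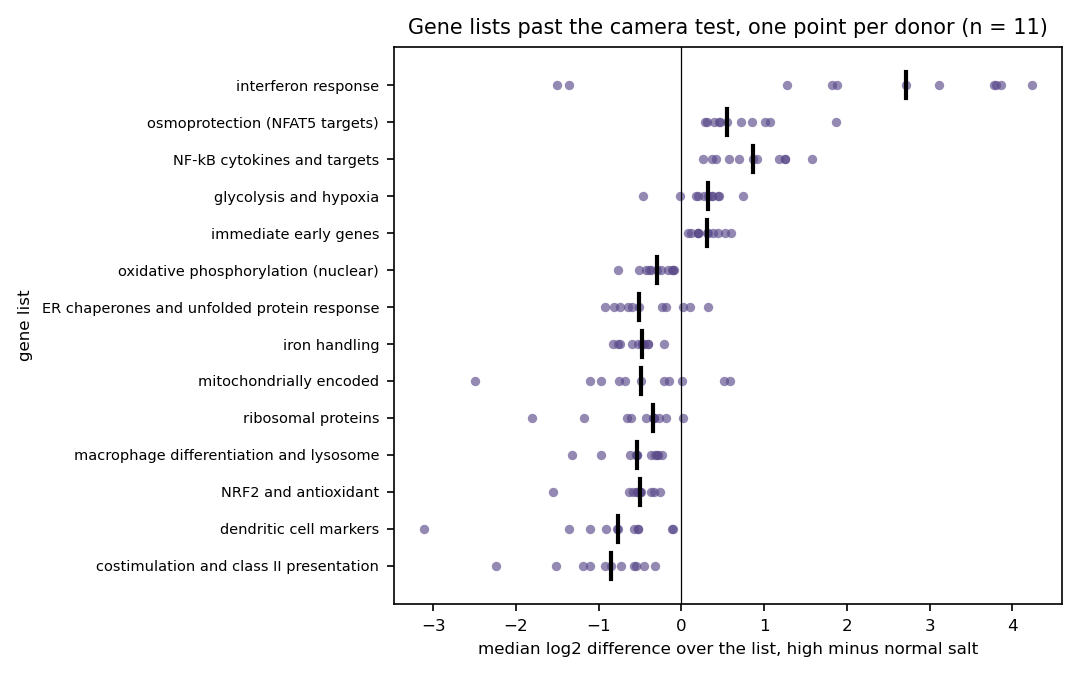
Median log2 difference between high and normal salt (x axis) over the members of the 14 lists past camera (y axis); each point is 1 of 11 donors and black bars are medians over donors. Osmoprotection, NF-kB and immediate early genes lie above 0 in all 11 donors and class II presentation, iron handling, NRF2, macrophage, dendritic and oxidative phosphorylation genes below 0 in all 11, while the interferon response lies above 0 in 9.

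The authors' deposited table lists 19199 genes and holds 2776 genes higher and 2356 lower at an adjusted p below 0.05 in its protein-coding fit, and 2207 higher and 2458 lower in its fit on all features. The authors' deposited table shares 11984 genes with the edgeR test; 93.7% of them had the same direction in the protein-coding fit. Of 4963 edgeR calls in the authors' deposited table, 4300 were also past its threshold and 0 were past it in the opposite direction. For SLC5A3 the authors' deposited table gives a log2 fold change of 4.67 in the protein-coding fit, and for CLLU1-AS1 7.30. It places JAK2 past the threshold in the protein-coding fit (0.35, adjusted p = 0.0325) and not in the fit on all features of the authors' deposited table (0.31, adjusted p = 0.0879).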

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

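DESeq2, limma trend, library totals without TMM factors, mitochondrial genes left out, the omission of donors 5 and 9 together, protein-coding genes alone and thinned libraries were chosen after seeing the data. Camera with an estimated correlation and fry were set beside camera in the design, before the data were seen, as were the other alternatives. Of 5602 genes changed, the count was 2245 at 1.5-fold or more and 802 at 2-fold or more, both smaller by construction. Without the donor block it was 2249, 1185 higher and 1064 lower. There, 2237 of the 5602 calls were kept with the same sign, and 1 of the 5602 genes had the opposite sign, whether past the threshold or not. Library totals gave 5791 genes, with 1917 lower and 3874 higher, and kept 4631 of the calls. The cause of the shift was not tested. The other settings gave 4740 (stricter filter) to 6823 genes (library quality weights), with 6216 by DESeq2, 5502 by the signed-rank test, 5360 with libraries thinned to the smallest total and 6285 without donors 5 and 9 (3073 higher and 3212 lower). Leaving out each donor in turn gave 4743 to 6101 genes, 2311 to 3071 higher and 2432 to 3030 lower. Camera called 14 lists, 0 with an estimated correlation (which by construction allows for genes that move together) and 12 to 17 in the other settings, 13 to 15 with each donor left out. Named genes were scored as unchanged in 2069 comparisons, fell short of the threshold in 79 and passed it newly in 9 (with each donor left out, 1647, 65 and 4). For genes not past the threshold in the main test, a change of sign was also scored as unchanged. JAK2 lost its call in 11 settings, STK39, FOSL1 and ANGPTL4 in 10 each, XCR1 in 9, VCAN and PHLDA3 in 8, PTGES and MT-ND5 in 7 and CCNB2 in 6, while SCNN1D passed newly in 8. The classical monocyte list passed in 7 settings. Of named genes and lists past their test, 0 changed sign in any setting. With library totals the list medians of integrins (0.02), JAK-STAT (0.10), heat shock (0.10) and non-classical monocytes (0.06) turned from below to above 0. A pseudocount of 0.1 on FPKM and rescaling to TPM were not run, since the table holds counts, and the signed-rank test was not run on lists.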

Other observations

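The T and NK cell marker test, the fry splits and the 27 gene families below were chosen after the results were seen. Polyadenylated transcripts of histone genes, whose proteins package DNA, rose in 15 of 27 cases and fell in 2 (median 0.88, above 0 in 11 of 11 donors). Histone transcripts that are not polyadenylated were outside this measurement. H2AC25 (2.11 ± 0.43), H2BC5 (2.01 ± 0.20) and H2AC6 (1.86 ± 0.16) rose, and H3C10 (-0.87 ± 0.29) and H3-3B (-0.26 ± 0.09) fell. Camera gave an adjusted p of 9.78e-06 over the families, an estimated correlation an adjusted p = 0.172, and fry an adjusted p of 5.07e-05. Genes with a CLEC symbol, which include C-type lectin receptors but also other genes, rose in 7 of 13 cases and fell in 2 (camera adjusted p = 0.0263, but adjusted p = 0.172 with an estimated correlation; fry adjusted p = 8.74e-05), with CLEC5A (1.38 ± 0.32) and the beta-glucan receptor CLEC7A (1.18 ± 0.14) higher and CLEC17A (-0.97 ± 0.24) lower.

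Cathepsins, the lysosomal proteases, fell in 9 of 13 cases and rose in none (median -0.74), among them CTSF (-1.23 ± 0.21), CTSB (-0.91 ± 0.17) and CTSS (-0.88 ± 0.17). Camera gave an adjusted p of 0.00257, an estimated correlation an adjusted p = 0.430, and fry an adjusted p of 0.00106. Subunits of the translation initiation factor EIF3 fell in 7 of 13 cases, with EIF3L (-0.87 ± 0.16) and EIF3E (-0.77 ± 0.17), and tetraspanins in 6 of 12, with TSPAN4 (-1.62 ± 0.15), and none of either rose. Camera gave adjusted p-values of 0.00292 and 0.00922, against adjusted p = 0.430 and 0.172 with an estimated correlation, and fry gave 5.47e-04 and 7.59e-05. The lysosomal fucosidase FUCA1 fell by -2.15 ± 0.22. Camera called 9 of the 27 families, 0 with an estimated correlation, and fry called 16.

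Chance can be excluded for the count of genes changed: 5602 with the real labels against at most 2412 in 99 other swaps of the salt labels within donors, so that 1 of 100 gave as many. The count of 2714 genes higher and that of 2888 lower were also each reached by 1 of 100, with 1370 in 1 direction the highest of the others. Chance is not excluded for the count of lists past camera: 14 with the real labels, and 15 in the highest other split, with 6 of 100 as large. Chance can be excluded for the count of lists past fry, with 19 against at most 11 and 1 of 100 as large. Fry does not compare a list with other genes, and 40.3% of all tested genes changed. The fry count therefore does not show that these lists differ from other genes.

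Of 61 ribosomal protein genes 49 fell, and of 48 oxidative phosphorylation genes 34 fell and 1 rose (adjusted p = 0.561 and 0.448 with an estimated correlation). A trend on transcript length and GC content was fitted to the other genes, using each gene's longest annotated transcript. At these lists it was 0.01 and 0.03. With it removed the medians were -0.56 (95% bootstrap interval -0.61 to -0.50) and -0.37 (-0.42 to -0.27). These intervals, and those below without donors 5 and 9, resample genes and not donors. Genes of these lists move together (estimated correlation 0.92 and 0.44), so the intervals do not cover the spread between donors. Median annotated lengths were 2021 and 1677 bases, against 3672 over all genes. A bias that follows annotated length and GC does not account for the falls. One that follows the lengths of the expressed transcripts was not tested. Poor RNA in the libraries of donors 5 and 9 is excluded as the whole cause too, since without both donors the medians were -0.34 (-0.39 to -0.26) and -0.27 (-0.32 to -0.23), although the ribosomal median moved from -0.54. Reads lost to processed pseudogenes were not tested, and an effect of salt itself stays open.

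All 27 tested interferon genes rose, with an adjusted p = 0.448 for the list with an estimated correlation. The libraries of donors 5 and 9 do not account for it: their list medians, -1.35 and 1.83, lie below the median over donors (2.72), and without both the list median was 2.88 (2.15 to 3.16). Bootstrap intervals in this paragraph resample genes and not donors. RNA from T or NK cells, which the negative selection of monocytes is meant to remove, stays open: the 25 listed markers, fitted without a filter, had a median of -0.14 (-0.45 to 0.09), and the 8 above the filter one of -0.40 (-0.79 to -0.19). The interferon list median was above 0 in 9 of 11 donors and above 1 in 9, and ran from -1.50 to 4.23. The list thus rose in most donors. The limit set beforehand to exclude a response of only a few donors asked for more above 0, so by that limit the question stays undecided. The rise was not shared by all: donors 5 (-1.35) and 10 (-1.50) went the other way. Interferon transcripts were near the floor, with 31 counts of IFNB1 over the normal and 22 over the high salt libraries.

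MRPS6, a mitochondrial ribosomal protein gene, rose by 3.42 ± 0.24 in 11 of 11 donors, while the other 77 genes of its kind had a median of -0.12 (-0.92 to 0.46). Reads of SLC5A3, whose exons overlap those of MRPS6 on the same strand, may account for it: over 11 donors the log2 differences of both correlated at r = 0.82 (permutation p = 0.0019, adjusted p = 0.0038 over 2 relations; Spearman rho 0.89, p = 4.9e-04). Without the 2 donors whose SLC5A3 difference lay farthest from its median r was 0.81. The gain of MRPS6 in CPM was 17.7% of that of SLC5A3. Shared regulation of both genes was not tested.

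A hypothesis of slower maturation from monocyte to macrophage predicts that donors with a larger rise of the classical monocyte list show a larger fall of the macrophage list. In the macrophage list 20 of 29 members fell and 3 rose, and in the classical monocyte list 5 of 14 rose and none fell (adjusted p = 0.444 and 0.360 with an estimated correlation; camera adjusted p = 0.0633 for the latter). The macrophage median was above 0 in 0 of 11 donors and the classical monocyte median in 10 of 11, so the lists moved in opposite directions in most donors. Whether the sizes of these changes go together is a separate question. The correlation of the list medians over donors was r = 0.22 (permutation p = 0.525; Spearman rho 0.17, p = 0.617), which leaves the hypothesis undecided with 11 donors.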
